A study of Danio rerio with 3 samples.

How the data were processed

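Whole zebrafish larvae of the AB background were sampled at 3 days post-fertilization, in 3 libraries of 1 group each: control, HRAS and NICD. Per the labels' protocols, 10 ug of total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Per the series' design text, they were sequenced on an Illumina HiSeq 2000 and reads were assigned with CLC bio Assembly Cell 3.2 to the Ensembl release 63 transcripts of the zebrafish assembly Zv9. CASAVA 1.8 is named in the submitters' processing notes. Mapping parameters, and whether strand was used, are not given in the sources used here.

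The authors deposited for each library a table of 27882 gene identifiers, with read counts of unique and of non-unique reads, an expected count called corrected total reads per the file headers, and RPKM. The corrected reads hold the unique reads and a share of the non-unique reads, as whole numbers. The deposited RPKM values were recomputed from corrected reads, longest transcript length and library total, and differed by at most 0.268%. Unique reads made up 50.9% of corrected reads in the control, 50.3% in HRAS and 51.0% in NICD. A read shared by several transcripts of 1 gene also counts as non-unique: the median unique share was 100.0% in genes with 1 transcript and 23.2% in genes with more, so a low unique share does not by itself show sharing between genes. Names were found for 19635 identifiers (70.4%), of which 10184 have capital, human-style names that do not tell paralogs apart. Of the symbols on the gene lists 218 were not matched, among them mpx, kdrl, her6, her9 and il1b. No genome was used, and no coordinates are given.

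Corrected reads were scaled with TMM factors (edgeR 4.0.16, R 4.3.3) of 0.994 for control, 1.00 for HRAS and 1.01 for NICD. The ratio of each gene was taken on scaled counts after adding 0.5 reads to each library. A gene was called when it had at least 50 reads in the 2 libraries summed, differed by at least 2-fold and had an exact conditional binomial (Clopper-Pearson) 95% interval excluding 1. Interval and floor cover counting error only, and leave out the spread between larvae and the assignment of non-unique reads. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. A count of 3 reads corresponds to 0.114 CPM in the control, 0.073 CPM in HRAS and 0.136 CPM in NICD. For 41 gene lists, the median log2 ratio of members with at least 20 reads was set against 10000 random lists of the same size matched on expression in 20 bins (seed 1), and a list stood apart below percentile 2 or above percentile 98. The random lists hold unrelated genes, and members of a list that are expressed together reach extreme percentiles more readily. The list of adult globins had no measured member. Intervals of medians come from 1000 bootstrap draws of members. The agreement of the comparisons with the shared control was set beside 100 simulated sets of unchanged libraries.

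These designs, lists and alternatives were chosen before the data were examined. The calculation was revised once after first results had been seen: the 0.5 reads had been scaled with depth, and were then added unscaled as the design had stated. Both forms are compared in the closing section. At the same time the drawing of random lists was rewritten for speed, which altered the random draws. The genes named are those tied to the transgenes, a fixed set of blood, vessel, Notch, cell cycle and MAPK genes, the 10 highest and 10 lowest named genes of each comparison with at least 100 reads in the higher library, and up to 4 members of each list with the largest change. Not all genes the rule selects are described, and 1 of them is not reported here.

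The size rule was tested on simulated counts for each comparison. In HRAS against control it called 66 of 66 genes changed 4-fold and 18 of 20675 unchanged genes, in NICD against control 75 of 75 and 9 of 19868, and in HRAS against NICD 55 of 55 and 18 of 20654. Of 200 unchanged simulated lists, 5, 4 and 6 stood apart in these comparisons. The simulation holds counting noise alone and not the variation between clutches. Alternatives were total counts, DESeq2 1.42.0 size factors, upper quartile scaling, the authors' RPKM, totals without the 20 most abundant genes, unique reads, minimums of 10, 200 or no reads, 5 reads added, thinning to the smallest library, 1.5-fold and 4-fold limits, and 50 bins.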

Results

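Messenger RNA of whole zebrafish larvae was sequenced at 3 days post-fertilization in 3 libraries, 1 per group. The control larvae were wild type. The HRAS larvae carried a GAL4 driver under an endothelial fli1 promoter together with a UAS transgene for eGFP fused to the oncogenic human HRASV12. The NICD larvae carried the same driver together with a UAS transgene for the Notch intracellular domain, the active fragment of a Notch receptor. No GAL4 driver was named for the control, so the effect of the driver was not separable from that of either transgene. The control library held 26384466 corrected reads, the HRAS library 41105619 and the NICD library 21944303. With 1 library in each group no difference had a replicate check, and no p-value was computed. Every comparison is therefore between these libraries and not between the conditions. A gene was called higher or lower by a size rule of at least 2-fold, and the bracketed range after a fold is its exact conditional binomial 95% interval, which covers counting error only.

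The first comparison asked how expression of HRASV12 in the endothelial lineage changed the larval transcriptome. Of 20873 genes with at least 50 reads in both libraries summed, 1272 were higher and 865 were lower in the HRAS library than in the control. Genes of the vascular endothelium and of myeloid cells were among those higher, and genes of the retina were among those lower. The endogenous gene named HRAS had 907 reads in the control and 1542 in the HRAS library, a fold of 1.08 [0.999 to 1.18]. The transgene encodes a human protein, and whether its reads were counted under this zebrafish gene is not given in the sources used here, so this value does not check the label.

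Pan-endothelial genes had a median log2 ratio of 1.04 (bootstrap 95% interval over members 0.75 to 1.46) in HRAS against control, above all 10000 random lists matched on expression. Of the 40 measured members, 21 were higher and 2 were lower. FLI1, an endothelial transcription factor whose promoter drove the transgene, was 2.45-fold higher [2.29 to 2.62]. The gene cdh5, which encodes VE-cadherin of endothelial junctions, was 2.07-fold higher [1.89 to 2.26], although almost none of its reads were unique. The ratios were uneven: rasip1, an endothelial RAS-interacting protein, was 11.5-fold higher [9.86 to 13.6], ecscr, an endothelial surface protein, was 9.07-fold higher [7.22 to 11.7], and plvapa stood at 0.127 of its control level [0.0836 to 0.183]. Venous and lymphatic genes had a median log2 ratio of 1.43, with 6 of 12 members higher and 0 lower. Among them lyve1a was 10.9-fold higher [9.03 to 13.4], and the scavenger receptor gene stab2 was 3.67-fold higher [3.43 to 3.94]. Arterial genes had a median of 0.01, with 1 of 21 members higher and 1 lower, and did not stand apart from random lists.

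**Figure D1:**
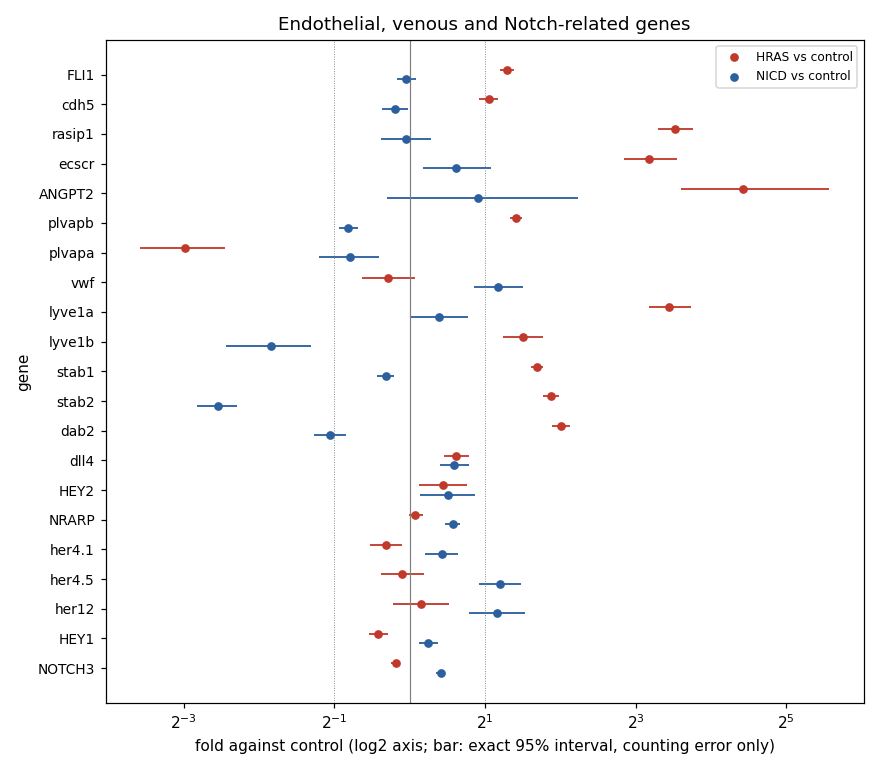
Fold against the control library for endothelial, venous and Notch-related genes (log2 axis) in the HRAS library and the NICD library. Points are folds, bars are exact 95% intervals for counting error only, and dotted lines mark 2-fold; stab2 lies at 3.67 in HRAS and at 0.171 in NICD.

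Neutrophil and granulocyte genes had a median log2 ratio of 1.01, with 11 of 24 members higher and 1 lower. The metalloprotease genes MMP9 and mmp13a were 11.8-fold [10.6 to 13.2] and 8.54-fold [7.5 to 9.81] higher, and both are also on the list of inflammation genes. The lysozyme gene lyz, a myeloid marker, had a fold of 1.14 [1.05 to 1.24] and was not called. Macrophage and microglia genes had a median of 0.84, with 11 of 28 higher, and pan-leukocyte genes a median of 0.86, with 6 of 18 higher. The actin-bundling gene LCP1 was 3.82-fold higher [3.42 to 4.29] and the myeloid transcription factor gene SPI1 2.97-fold higher [2.38 to 3.77]. Erythroid genes other than globins had a median of 0.34, with 4 of 30 higher and 1 lower. In this group alas2, the first enzyme of haem synthesis in red cells, was 2.04-fold higher [1.92 to 2.17], while gata1a had a fold of 1.62 [1.29 to 2.07] and was not called. Larval globin genes had a median of 0.54, with 3 of 7 higher, among them hbbe3 at 3.78-fold [3.18 to 4.54]. Haematopoietic stem and progenitor genes had a median of 0.00, at percentile 48.2, with 4 of 25 higher and 1 lower. The higher members were ERG, at 5.79-fold [4.49 to 7.71], LMO2, at 2.87-fold [2.46 to 3.36], gata2b, at 2.53-fold [1.4 to 5.2], and FLI1, and the lower one was a gene named CXCR4. RUNX1 had only 13 reads in the control and 7 in the HRAS library.

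RAS/MAPK response genes had a median log2 ratio of 0.77, with 16 of 36 members higher and 0 lower. FOSL1, a subunit of the AP-1 transcription factor, was 9.66-fold higher [7.59 to 12.7], DUSP5 was 4.64-fold higher [3.99 to 5.44], and DUSP6, a phosphatase of ERK, was 2.06-fold higher [1.98 to 2.15]. Inflammation genes had a median of 1.27, with 16 of 28 higher, among them cxcl18b at 5.31-fold [3.79 to 7.82]. S phase genes had a median of -0.30, below nearly all random lists, but 0 of 23 members passed the size rule, and PCNA stood at 0.81 of its control level [0.785 to 0.836]. Genes of the p53 and senescence list had a median of 0.39, with 8 of 31 higher, whereas cdkn1a had a fold of 1.12 [0.949 to 1.32].

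Notch target genes had a median log2 ratio of -0.38 in HRAS against control, at percentile 0.22 of random lists, but the bootstrap interval over members ran from -0.50 to 0.17 and included 0. Of 21 measured members 0 were higher and 1, HES2, was lower. It stood at 0.424 of its control level [0.277 to 0.636] on 62 and 41 reads, none of them unique. The median turned to 0.08 over 15 members when only those with at least 200 reads were kept, so the lower median depended on including members with fewer reads. The members kept went both ways. Among them her8a stood at 0.57 [0.474 to 0.685], HEY1 at 0.749 [0.689 to 0.815] and her4.1 at 0.804 [0.694 to 0.933], whereas HEY2 stood at 1.35 [1.09 to 1.7]. Neural genes had a median of -0.51, with 2 of 35 lower. Notch receptors and ligands had a median of -0.01, with none of 9 called, NOTCH3 stood at 0.878 [0.844 to 0.912] and dll4 at 1.54 [1.37 to 1.73]. In the core Notch pathway list, 1 of 17 genes was called: mfng, a Fringe glycosyltransferase, was 3.35-fold higher [2.69 to 4.26].

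Photoreceptor and retina genes had the lowest median of the lists, at -1.58, with 22 of 30 members lower and 0 higher. The cone transducin gene GNAT2 stood at 0.152 of its control level [0.144 to 0.159]. Cartilage and bone genes had a median of -0.43, with 6 of 26 lower and 1 higher, and exocrine pancreas genes a median of -0.64, with 6 of 19 lower. Reference genes had a median of 0.06 and did not stand apart.

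The second comparison asked how the Notch intracellular domain under the same driver changed the transcriptome. Of 20061 genes, 715 were higher and 626 lower in the NICD library than in the control. Notch target genes had a median log2 ratio of 0.23, at percentile 93.7, and did not stand apart from random lists. Of 21 members 2 were higher and 1 was lower. The higher members were the hairy-related genes her4.5, at 2.29-fold [1.9 to 2.78], and her12, at 2.23-fold [1.73 to 2.88], and most reads of both were not unique. HES2 was lower at 0.447 of its control level [0.261 to 0.722], and none of its reads were unique. Notch receptors and ligands had a median of 0.35, above percentile 98, with none of 9 members called and a bootstrap interval from -0.17 to 0.52, and this list did not stand apart on unique reads. NOTCH1, which stands for 1 identifier here, had 1326 reads in the control and 1426 in the NICD library, a fold of 1.28 [1.19 to 1.38]. Its log2 ratio of 0.35 is the median of this list, and only 17 of its reads in each of these libraries were unique. Whether reads of the NICD transgene were counted under a Notch receptor gene is not given in the sources used here. Neither the list median nor this fold therefore checks the label.

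Pan-endothelial genes had a median log2 ratio of 0.04 in NICD against control, with 1 of 40 members higher, and cdh5 had a fold of 0.873 [0.773 to 0.984]. Arterial genes had a median of 0.28, at percentile 99.3, but 0 of 21 members were higher and 1, AQP8, was lower, and the list did not stand apart on unique reads. Venous and lymphatic genes had a median of -0.25, with 3 of 11 members lower: stab2 stood at 0.171 [0.141 to 0.205], lyve1b at 0.28 [0.185 to 0.405] and dab2 at 0.48 [0.413 to 0.555]. The percentile of this median was 1.99, at the limit of 2, and it lay under 2 with 12 of 20 seeds of the random lists, so whether the list stood apart was not settled. On unique reads the median was -0.10, at percentile 27.6, and with a minimum of 200 reads it was -0.090, at percentile 20.2. Unique reads in control and NICD numbered 60 and 25 for stab2, 74 and 28 for lyve1b, and 22 and 20 for dab2. The folds of stab2 and dab2 thus rest mostly on reads that were not unique.

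Inflammation genes had a median log2 ratio of 0.85, with 10 of 28 higher in the NICD library, and neutrophil genes a median of 0.80, with 5 of 23 higher. MMP9 was 4.09-fold higher [3.62 to 4.64]. Macrophage and microglia genes had a median of 0.09, with 1 higher and 1 lower of 23, and on unique reads the median was -0.27. RAS/MAPK response genes had a median of 0.28, with 4 of 36 higher, FOSL1 at 2.77-fold [2.08 to 3.77] among them. Erythroid genes other than globins had a median of -0.05 with 1 of 30 higher. S phase genes had a median of -0.59 with 2 of 23 lower, MCM3 at 0.367 [0.328 to 0.408] and RRM2 at 0.483 [0.435 to 0.535]. Photoreceptor genes had a median of -1.30 with 17 of 31 lower, and GNAT2 stood at 0.208 [0.197 to 0.221]. Exocrine pancreas genes had a median of -0.53 with 3 of 19 lower and 0 higher, and cartilage and bone genes a median of 0.39 with 1 of 25 higher. Among genes with a name, the highest ratio was that of actc1c, an actin gene, with 9 reads in the control, 4 in HRAS and 4957 in NICD, and most of them were not unique.

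**Figure D2:**
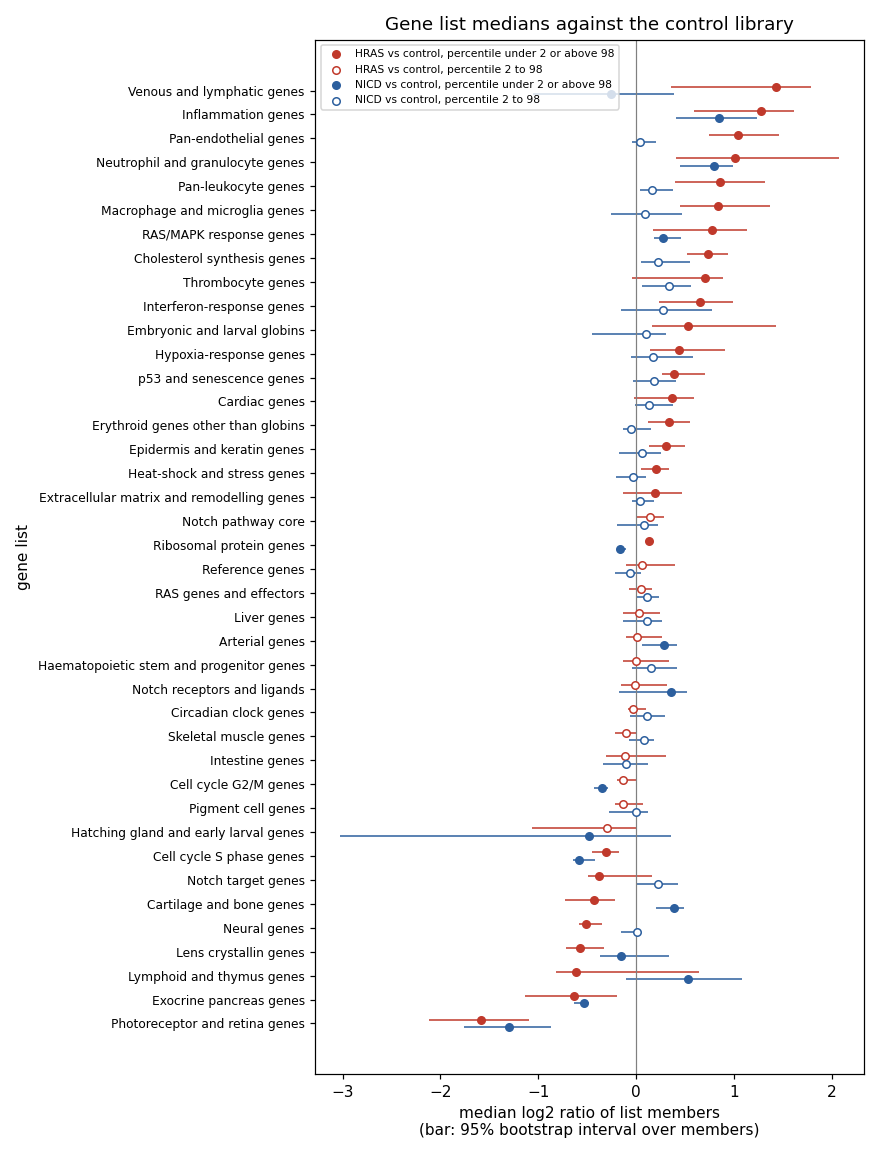
Median log2 ratio of 40 gene lists for HRAS against control and for NICD against control, with bars for the 95% bootstrap interval over list members. Filled points have a percentile under 2 or above 98 among 10000 matched random lists; pan-endothelial genes lie at 1.04 in HRAS and 0.04 in NICD, and photoreceptor genes at -1.58 and -1.30.

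The direct comparison of both transgenic libraries, which share the driver, gave 1075 genes higher and 1291 lower in HRAS than in NICD, of 20856. Pan-endothelial genes had a median log2 ratio of 0.97, with 20 of 40 higher and 3 lower, and venous and lymphatic genes a median of 1.66, with 6 of 12 higher. Macrophage genes had a median of 0.64, with 10 of 27 higher and 1 lower, a gene named MPEG1 at 0.331 [0.295 to 0.37] that was 5.23-fold higher [4.46 to 6.18] in NICD than in the control. A second identifier of that name was 2.56-fold higher [2.14 to 3.1] in HRAS than in NICD. Larval globins had a median of 0.85, with 3 of 7 higher. Notch target genes had a median of -0.49 (bootstrap 95% interval -0.66 to -0.08), at percentile 0.08, with 0 higher and 3 lower of 21. Neural genes also had a lower median, at -0.38 (bootstrap 95% interval -0.60 to -0.20), below all random lists, with 0 higher and 3 lower of 35. Cartilage and bone genes had a median of -0.94, with 11 of 26 lower and 1 higher.

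The log2 ratios of HRAS and NICD against the control had a Pearson r of 0.43 and a Spearman correlation of 0.34 across 21603 genes, which are not independent replicates. Both ratios use the same control library, and simulated unchanged libraries gave a mean Pearson r of 0.53. The covariance was 0.233 against 0.019 in the simulation, a difference of 0.214. Genes higher in both numbered 287, where independent lists would share 27.6 and the simulation gave 0.34, and genes lower in both numbered 240, against 26.5 and 0.19. The simulation holds counting noise alone, so almost no gene passes 2-fold in it. Part or all of the overlaps and of the covariance may come from the single control library, which could not be split.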

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

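The tests of explanations in this part were chosen, and some of their criteria revised, after the results had been seen, whereas the list medians and the minimum of 200 reads were planned. In 4 lists the medians of HRAS and of NICD against control had opposite signs and both lay outside the percentile limits, and the difference between them was not tested. Venous and lymphatic genes had a median log2 ratio of 1.43 in HRAS and -0.25 in NICD against control, the latter at the limit of the percentile rule and nearer 0 on unique reads (-0.10) and with a minimum of 200 reads (-0.090), where the list no longer stood apart. Cartilage and bone genes had medians of -0.43 and 0.39, lymphoid and thymus genes -0.61 and 0.53, and ribosomal protein genes 0.13 and -0.16. The bootstrap intervals of the lymphoid medians, -0.82 to 0.64 in HRAS and -0.10 to 1.09 in NICD, both include 0. That of the venous median in NICD, -1.06 to 0.39, includes 0 too. The lymphoid list in NICD no longer stood apart on unique reads (0.48) or with no minimum of reads (0.29), and the ribosomal list in NICD no longer stood apart with 50 bins (percentile 7.86). Single genes that passed the size rule in opposite directions numbered 12 that were higher in HRAS and lower in NICD, and 12 that were lower in HRAS and higher in NICD. Independent lists would share 27.6 and 26.6, and simulated unchanged libraries gave 0 of both; the former leaves out the shared control and the latter any effect, so neither says whether 12 is many or few. Those higher in HRAS and lower in NICD include stab2, dab2, lyve1b and sele. None of the reads of sele were unique, and dab2 had 22 unique reads in the control and 20 in NICD. GPR182, CALCRL and OIT3 are in the same set, and all of their reads were unique. GPR182 was 5.71-fold higher in HRAS [5.01 to 6.55] and stood at 0.409 of its control level in NICD [0.314 to 0.524].

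The endothelial genes higher in the HRAS library were tested for technical sources. An error of scaling would move matched random lists as far as the pan-endothelial list, whose median log2 ratio exceeded theirs by 1.04 (bootstrap 95% interval over members 0.75 to 1.46), which argues against it. On unique reads the median was 0.88 over 32 members, with an interval from 0.34 to 1.48, which lies above 0 but is wide, so a part played by reads shared between gene copies stays open. The driver alone is not excluded: the NICD library, with the same driver, had a median of 0.037, but NICD could offset an effect of the driver, and no library with the driver alone was analysed. More endothelial cells and more expression per cell cannot be told apart in RNA of whole larvae. If more cells with unchanged expression were the whole cause, no member would be lower and most counting intervals would include the median fold. Of the 40 members 2 were lower, and the intervals of 17.5% included the median fold. Counting intervals leave out the spread between larvae, and genes also expressed in other tissues would be diluted. With 1 library per group these values therefore do not exclude it.

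The photoreceptor genes lower in both transgenic libraries share 1 control. The HRAS against NICD median was -0.32, and a control library that stands apart cannot be told apart from an effect common to both transgenic lines, since 1 control was analysed. A general delay of development stays open. S phase genes, assumed here to be higher in younger larvae, had medians of -0.30 in HRAS and -0.59 in NICD, which goes against a delay. Exocrine pancreas genes, another differentiated tissue, had medians of -0.64 and -0.53, both below all random lists, which goes with it. Cartilage and bone genes had medians of -0.43 in HRAS, which goes with a delay, and 0.39 in NICD, which goes against it. Another time of day at collection would be expected to move clock genes, whose median absolute log2 ratio was 0.16 in HRAS and 0.18 in NICD, against 1.58 and 1.36 for the photoreceptor genes. A delay of the retina alone or of several tissues and an effect of the transgenes stay open.

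The lower Notch target median of the HRAS library is consistent with a smaller share of neural RNA: the Notch target median exceeded the neural median by 0.13 (bootstrap 95% interval -0.04 to 0.67). The median differed from that of matched random lists by -0.39, with an interval from -0.50 to 0.16, and on unique reads it was -0.35 over 17 members, with an interval from -0.58 to 0.12. Scaling moves all genes alike, so the difference from the random lists is free of it, but the interval of that difference includes 0. Other scalings shifted HRAS against control by only -0.016 to 0.013. The random lists had a median of 0.009, but TMM places most genes near 0 by design, so this value cannot exclude scaling. The intervals of the difference and of the unique-read median include 0 and reflect the spread between members. Whether the list as a whole was lower is therefore not settled. Shared reads stay open as a source. Since the median turned to 0.08 with a minimum of 200 reads, lower expression of Notch targets by HRAS is a hypothesis that these libraries leave open.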

How the results depend on the processing

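The alternatives listed as unique reads for named genes and agreement, and 0.5 reads scaled with depth, were chosen after seeing the data. Numbers of called genes were within 1.5 times of the main numbers under every scaling, unique reads, 5 reads added and thinning, and depended on the minimum of reads and the fold limit by construction. With a 1.5-fold limit, 2709 genes were higher and 2274 lower in HRAS against control, 2133 genes were higher and 1577 lower in NICD against control, 2310 genes were higher and 2957 lower in HRAS against NICD. With a 4-fold limit, 291 genes were higher and 134 lower in HRAS against control, 132 genes were higher and 116 lower in NICD against control, 237 genes were higher and 152 lower in HRAS against NICD. With a minimum of 200 reads, 669 genes were higher and 452 lower in HRAS against control, 258 genes were higher and 289 lower in NICD against control, 521 genes were higher and 700 lower in HRAS against NICD. With a minimum of 10 reads, 1861 genes were higher and 1346 lower in HRAS against control, 1293 genes were higher and 1060 lower in NICD against control, 1629 genes were higher and 1870 lower in HRAS against NICD. With no minimum, 1933 genes were higher and 1550 lower in HRAS against control, 1457 genes were higher and 1139 lower in NICD against control, 1655 genes were higher and 2095 lower in HRAS against NICD. The covariance of both sets of ratios was 0.417 with a minimum of 10 reads, 0.137 with 200 and 0.177 on unique reads. Genes higher in both numbered 521 and 113 with minimums of 10 and 200 reads, and genes lower in both 401 and 135. Among list medians, 1519 of the recomputed values kept their side of the percentile limits and, where the list stood apart, their sign. This count includes the values under other scalings, which could hardly change, because scaling moves a list and its random lists alike. On unique reads 105 values kept their side and sign. The values that did not are given below as medians on the log2 scale, and the cause was not tested. Under upper quartile scaling, Venous and lymphatic in NICD against control (-0.28) no longer stood apart. Under unique reads, Thrombocyte in HRAS against NICD (-0.19) changed sign. Under unique reads, Thrombocyte in HRAS against control (0.31), Cardiac in HRAS against control (0.24), Notch receptors and ligands in NICD against control (0.026), Lymphoid and thymus in NICD against control (0.48), Arterial in NICD against control (0.24), Venous and lymphatic in NICD against control (-0.10), Lens crystallin in NICD against control (-0.029), Skeletal muscle in HRAS against NICD (-0.066) no longer stood apart. Under unique reads, Intestine in HRAS against control (-0.29), Hatching gland and early larval in HRAS against control (-0.47), p53 and senescence in NICD against control (0.26), Cell cycle S phase in HRAS against NICD (0.28), Interferon-response in HRAS against NICD (0.68) newly stood apart. Under unique reads, Macrophage and microglia in NICD against control (-0.27) stood apart with the other sign. Under a minimum of 200 reads, Notch target in HRAS against control (0.078), Lens crystallin in NICD against control (0.11) changed sign. Under a minimum of 200 reads, Interferon-response in HRAS against control (0.28), Venous and lymphatic in NICD against control (-0.090), Neutrophil and granulocyte in HRAS against NICD (0.20) no longer stood apart. Under a minimum of 200 reads, Thrombocyte in NICD against control (0.42), Hypoxia-response in NICD against control (0.27), Cell cycle S phase in HRAS against NICD (0.23), Hatching gland and early larval in HRAS against NICD (0.48) newly stood apart. Under a minimum of 200 reads, Exocrine pancreas in HRAS against NICD (0.34) stood apart with the other sign. Under no minimum, Interferon-response in HRAS against control (0.38), Lymphoid and thymus in NICD against control (0.29), Thrombocyte in HRAS against NICD (0.10) no longer stood apart. Under no minimum, Hatching gland and early larval in HRAS against NICD (0.48) newly stood apart. Under 5 reads added, Lens crystallin in NICD against control (-0.085) no longer stood apart. Under 5 reads added, Interferon-response in HRAS against NICD (0.30) newly stood apart. Under thinning, Venous and lymphatic in NICD against control (-0.22), Lymphoid and thymus in HRAS against NICD (-0.47) no longer stood apart. Under thinning, Thrombocyte in NICD against control (0.48), Cell cycle S phase in HRAS against NICD (0.23) newly stood apart. Under 50 bins, Venous and lymphatic in NICD against control (-0.25), Ribosomal protein in NICD against control (-0.16) no longer stood apart. Under 50 bins, Skeletal muscle in NICD against control (0.081) newly stood apart. Under 0.5 reads scaled with depth, Venous and lymphatic in NICD against control (-0.25) no longer stood apart. Of the recomputed ratios of named genes, 5836 stayed within the counting interval and 252 moved outside it, and no called gene changed sign. Most of the moves were on unique reads, where 190 ratios moved outside the interval and 603 stayed within it. For 78 of 353 named genes fewer than 50 unique reads were present in HRAS and control, and no value on unique reads was computed for such genes. With 0.5 reads scaled with depth, the form first used, 1281 genes were higher and 862 lower in HRAS against control, 712 and 628 in NICD against control, and 1088 and 1277 in HRAS against NICD. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible for the same reason. A count of 3 reads corresponds to 0.136 CPM in the NICD library, the shallowest, and to 0.073 CPM in the HRAS library, the deepest.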

Other observations

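The tests of hypotheses in this part were chosen after the results had been seen, whereas the list medians were planned. Further lists stood apart in the HRAS library. Cholesterol synthesis genes had a median log2 ratio of 0.74 with 5 of 20 higher, among them SQLE, squalene epoxidase, at 3.06-fold [2.51 to 3.79]. Hypoxia-response genes had a median of 0.44 with 6 of 27 higher and 1 lower, igfbp1b at 10.3-fold [7.97 to 13.8]. Interferon-response genes had a median of 0.65 with 4 of 20 higher, and isg15 was 7.02-fold higher [3.74 to 16.6], but this list no longer stood apart with a minimum of 200 reads (0.28) or with no minimum (0.38). Heat-shock and stress genes had a median of 0.21 with 5 of 28 higher, hsp70.3 at 4.75-fold [4.18 to 5.42]. Lens crystallin genes had a median of -0.57 with 9 of 39 lower. The natriuretic peptide gene nppb was 6.83-fold higher in HRAS [4.01 to 13.6] and 6.39-fold higher in NICD [3.62 to 13]. In the NICD library the G2/M list had a median of -0.35 with none of 30 called, and the hatching enzyme genes he1.1 and he1.2 stood at 0.162 [0.134 to 0.194] and 0.123 [0.0809 to 0.176] of the control.

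A hypothesis that arterial genes follow the other endothelial genes in the HRAS library was not borne out for the list medians. With shared members left out, the arterial median was lower than the pan-endothelial one, with a difference of -1.12 (bootstrap 95% interval -1.59 to -0.71). Genes also expressed in other tissues would be diluted in RNA of whole larvae, so this difference does not show how arterial endothelium changed. For the NICD library the arterial median exceeded the venous one by 0.53, but the interval from -0.15 to 1.34 includes 0, so a different change of arterial and venous genes stays open.

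There were 40 genes with at least 100 reads in 1 library and 3 or fewer in another. Of the 24 with 1 transcript, 70.8% had under 50% of their reads unique, against 5.42% of 8675 other such genes. This is consistent with reads being divided differently between near-identical copies, and a strain difference between the lines, for which no genotype was analysed, might do the same. Examples are SCG5, fabp4a and LRRTM2, which had 0 reads in control and HRAS. On corrected reads they were at least 65.8-fold, 41.2-fold and 51.5-fold higher in NICD, against a floor of 3 reads in the control library. Of their reads in NICD, only 10 of 166, 15 of 104 and 6 of 130 were unique. These folds are no lower bounds where reads were divided differently between copies.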
